A study of Bos taurus with 43 samples.

How the data were processed

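Uterine luminal cells were collected with a cytology brush from 43 Angus x Brahman cows on day 4, with day 0 the last GnRH dose of the synchronization, and poly-A RNA from each cow was sequenced as 1 library on an Illumina NovaSeq, per the labels' protocols. RNA integrity numbers ranged from 5.6 to 8.7 on the Bioanalyzer and from 6.9 to 9.4 on the Qubit, per the labels' protocols, and were not given per cow. The authors deposited 1 table per library with raw read counts for 27570 Ensembl bovine gene identifiers, as the file headers and the whole-number values show. The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.4, HISAT2, HTSeq and the genome build ARS-UCD1.2. Their order, the HTSeq settings for strand and shared reads, and the annotation release are not given in the sources used here. Counts of overlapping or near-identical genes could therefore be split or lost, and this cannot be resolved per gene. The tables hold no HTSeq summary rows, so the share of reads outside genes is unknown.

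The files pair no identifier with a gene symbol, and the gene table used here (assembly ARS-UCD2.0) lists no Ensembl identifiers, so 0 identifiers were matched to a symbol. Genes are therefore given by identifier, without position or function. The 36 gene lists fixed before the data were examined (cell type markers, hormone response, metabolism, immune and cell cycle genes) could not be tested. Covariates built from the leukocyte and stromal lists could not be made either. The rule for named genes, also fixed before the data were examined, asked for the 12 genes of smallest p in each direction with a symbol and a mean log2 CPM of at least 0. Without symbols it was applied to identifiers and limited to 2 per direction and comparison. The genes that the rule named by symbol for the P4 comparison are not reported.

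Total counts per library ranged from 11159501 to 23572549 with a median of 15544498, and between 16705 and 18842 genes had at least 1 count. The 10 most abundant genes took 3.70% to 11.3% of a library. Genes at 0 in every library numbered 4448. After edgeR's filterByExpr (minimum count 10, smallest group 18), 15206 genes were tested. TMM factors ranged from 0.814 to 1.14.

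Cows were grouped by the pregnancy label, 25 pregnant and 18 nonpregnant, and by the block label (2 rounds of synchronization). Each cow is 1 independent sample. P4 (progesterone) was taken from the labels, which give no unit, and entered on the log2 scale. The main test was edgeR 4.0.16's quasi-likelihood F-test (robust glmQLFit, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. Outcome and block were fitted together, P4 was fitted with block, and the interactions of outcome with block and with P4 were fitted in models holding their main terms. Log2 fold changes are from these fits, with an SE taken as the absolute fold change divided by the square root of F and a 95% interval from the moderated degrees of freedom. CPM values use TMM-scaled library sizes. Log2 CPM with a prior count of 2 was used for principal components, for the classifier and for linear slopes under reassigned labels.

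P4 was compared between outcomes by a two-sided permutation test (100000 resamples within blocks), and within each block by an exact permutation test. Pregnancy rates were compared by Fisher's exact test with Wilson 95% intervals. Prediction of outcome used a diagonal linear discriminant on the 100 genes of largest statistic in each training fold, with 5-fold cross-validation repeated 20 times. Counts of called genes were set beside 100 assignments of the labels, the real one included, drawn within blocks or, for block, within outcomes.

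The scripts were tested on simulated data with known answers, in which counts for the 15206 genes were drawn from the real means, library sizes and dispersions and 200 genes were changed. In the simulated outcome comparison, 59.7% of genes changed by 1.5-fold, 79.1% of those changed by 2-fold and 92.4% of those changed by 3-fold were called in the right direction, with 5 false calls. In the simulated P4 comparison the shares were 74.6%, 91.0% and 100% for the same folds per doubling of P4, with 8 false calls. In the simulated block comparison they were 47.8%, 80.6% and 93.9%, with 2 false calls. Simulated genes vary independently of one another, unlike real ones.

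Alternatives fixed before the data were examined were DESeq2 1.42.0, limma 3.58.1 voom with sample weights, RLE factors, no low-count filter, a filter of CPM above 1 in at least 18 samples, other covariates, surrogate variables (sva 3.50.0), other scales of P4 and other classifier settings. Chosen after seeing the data were fits within a block or an outcome, fits with total counts, detected genes or the share of the 10 most abundant genes as a covariate, fits without the 7 libraries in which those 10 genes took over 8%, and fits leaving out each library in turn. Fits on part of the cows used the genes and TMM factors of the full set. Principal components, modules and the comparison of slopes between blocks were also added after seeing the data.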

Results

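Endometrial luminal samples from 43 beef cows were profiled by RNA sequencing in early diestrus, before each cow received 1 in vitro-produced embryo on day 7. Pregnancy was scored around day 30. The series asks how the luminal transcriptome of day 4 relates to that outcome. Of the 43 cows, 25 became pregnant and 18 did not. The first round of synchronization (block 1) held 11 pregnant and 10 nonpregnant cows, and the second (block 2) held 14 and 8. Libraries held between 11159501 and 23572549 counts, with a median of 15544498. Total counts, detected genes and the share of the 10 most abundant genes did not differ between outcomes past the threshold (two-sided permutation p = 0.806, 0.435 and 0.835).

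Progesterone (P4), the steroid of the corpus luteum that prepares the endometrium for pregnancy, was measured in blood on the day of sampling. P4 had a geometric mean of 0.808 in pregnant cows and 0.599 in nonpregnant cows, in the unstated unit of the labels. The difference was 1.35-fold (0.43 on the log2 scale), with SDs of 0.60 (n = 25) and 0.88 (n = 18) on that scale. It did not pass the threshold on the log2 scale fixed for the test (two-sided permutation p = 0.0664, within blocks), nor on the linear scale (p = 0.263), and passed on ranks (p = 0.0449). The fold was 1.31 in block 1 (exact permutation p = 0.318) and 1.39 in block 2 (exact permutation p = 0.0941). P4 differed little between blocks (1.03-fold, permutation p = 0.831). The pregnancy rate was 52.4% in block 1 (11 of 21 cows; 95% Wilson interval 32.4% to 71.7%) and 63.6% in block 2 (14 of 22 cows; 42.95% to 80.3%), and Fisher's exact test found no difference past the threshold (two-sided p = 0.543).

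**Figure D1:**
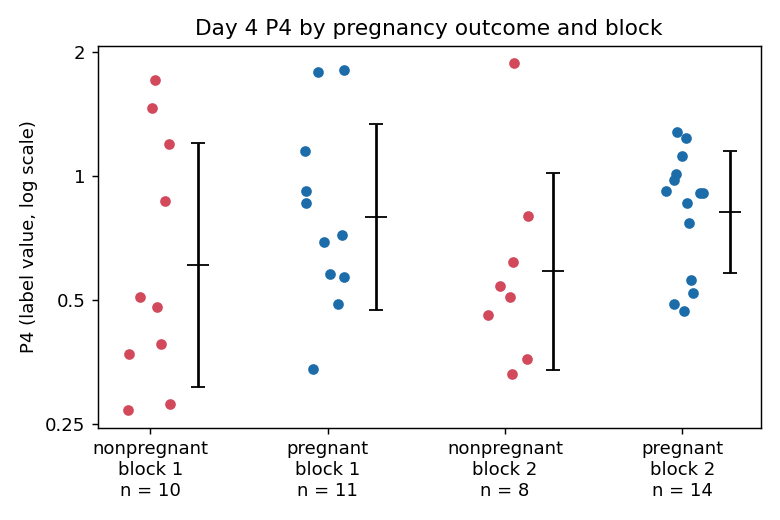
P4 on day 4 for each cow (points; log axis, label values without a unit) by pregnancy outcome and block; black marks show the geometric mean and 1 SD of log2 P4 on each side. Pregnant cows averaged 1.31-fold higher in block 1 and 1.39-fold higher in block 2, with wide overlap.

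The main comparison asks which genes of the luminal sample differed on day 4 between cows that later were or were not pregnant. No gene of the 15206 kept by the low-count filter passed (edgeR quasi-likelihood test with block in the model, 25 against 18 cows). At an unadjusted p under 0.05 there were 455 genes, where 760 would be expected with no difference and independent genes. DESeq2 and limma voom also called 0 genes, with 541 and 611 at an unadjusted p under 0.05. With no low-count filter edgeR called 5 genes, all lower in pregnant cows (1499 at an unadjusted p under 0.05 among 23122 tested). The genes of smallest p are therefore given as values, not as differences. ENSBTAG00000054069 averaged 3.77 ± 4.37 CPM in pregnant and 1.26 ± 0.712 CPM in nonpregnant cows (SD), a log2 fold change of 1.56 ± 0.46 (SE; edgeR adjusted p = 1.00). That value was 0.86 in limma voom, 0.94 with surrogate variables and 1.21 without pregnant replicate 16. The medians of this gene were 2.00 CPM in pregnant and 1.21 CPM in nonpregnant cows. Only 1 cow of block 1 and 2 of block 2 exceeded 10 CPM. ENSBTAG00000051506 averaged 11.8 ± 2.05 CPM in pregnant and 9.81 ± 1.49 CPM in nonpregnant cows (SD). ENSBTAG00000007053 averaged 28.4 ± 5.51 CPM in pregnant and 36.0 ± 8.71 CPM in nonpregnant cows (SD). ENSBTAG00000053542 averaged 3.66 ± 5.43 CPM in pregnant and 11.6 ± 27.3 CPM in nonpregnant cows (SD). Its log2 fold change of -2.29 ± 0.64 (SE) ranged from -2.91 to -1.09 over the alternatives, with -1.13 in limma voom, and was -1.59 without nonpregnant replicate 3 and -1.68 without nonpregnant replicate 15.

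The data bounded how large an outcome difference could be. The 95% interval of the log2 fold change had a median half-width of 0.28. It lay within a 2-fold change in either direction for 92.2% of the genes and within a 1.5-fold change for 73.2%. These intervals are per gene and not adjusted for the number of genes. Within block 1 the outcome comparison called 0 genes (408 at an unadjusted p under 0.05), and within block 2 it also called 0 (585). No gene passed the threshold for a difference between blocks in its outcome effect (0 called by edgeR's interaction test and by DESeq2 and limma voom, with 506, 582 and 878 at an unadjusted p under 0.05). The 95% interval of that difference was wider, with a median half-width of 0.56. It lay within a 2-fold change for 64.8% of the genes and within a 1.5-fold change for 33.3%. Across genes, which are not independent replicates, the outcome fold changes of block 1 and block 2 had a correlation of -0.14. Splits of the outcome within blocks gave correlations between -0.30 and 0.37 in the middle 90% of draws.

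**Figure D2:**
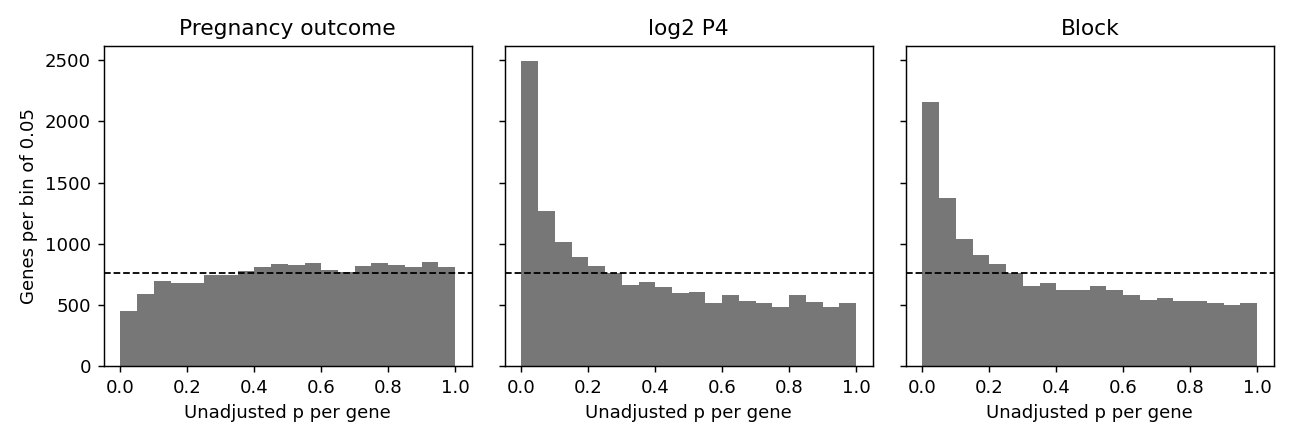
Distribution of unadjusted p-values over the 15206 genes for the outcome, P4 and block comparisons (bars, genes per bin of 0.05; dashed line, the count expected per bin with no difference). The outcome panel has 455 genes in its first bin, and the P4 and block panels have 2492 and 2156.

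Expression was next related to P4 itself, with block in the model. The level of 78 genes was associated with P4: 49 were higher and 29 lower in cows with more P4 (edgeR quasi-likelihood, adjusted p under 0.05, 43 cows). The absolute log2 change per doubling of P4 had a median of 0.41 among them and ranged from 0.13 to 2.59. ENSBTAG00000016819 rose 2.21-fold per doubling (log2 slope 1.15 ± 0.17 SE; edgeR adjusted p = 0.00034), from a median of 6.39 CPM in the 14 cows of lowest P4 to 23.8 CPM in the 14 of highest P4. ENSBTAG00000004256, an abundant transcript, rose 1.42-fold per doubling (0.50 ± 0.10 SE; edgeR adjusted p = 0.0148), with medians of 182 and 295 CPM in the same cows. ENSBTAG00000014555 fell to 0.391 of its level per doubling (-1.35 ± 0.24 SE; edgeR adjusted p = 0.00700), with medians of 2.67 and 1.09 CPM. Only 1 cow of block 1 and 3 of block 2 exceeded 10 CPM (highest 17.2), so its high values rested on few cows. ENSBTAG00000049346 fell to 0.459 of its level per doubling (-1.12 ± 0.19 SE; edgeR adjusted p = 0.00497), with medians of 1.75 and 0.425 CPM, and is thus a gene of low counts.

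All 78 slopes had the same sign in block 1, in block 2, in pregnant cows and in nonpregnant cows fitted alone, but the genes were chosen on these same cows. Fitted alone, block 1, block 2 and the pregnant cows each called 0 genes, and the nonpregnant cows called 1. In that order, 924, 3405, 739 and 2058 genes had an unadjusted p under 0.05. With no association and independent genes 760 would be expected, so the pregnant cows alone showed no excess. In these 4 fits the slopes had a median of 0.912, 1.15, 0.930 and 1.02 of their size in all cows, and SEs a median of 1.32, 1.51, 1.76 and 1.28 of theirs. Limma voom called 0 genes (1967 at an unadjusted p under 0.05), DESeq2 called 276, the fit with outcome as a covariate called 14, and the fit without the 7 libraries richest in their 10 most abundant genes called 7. In those last fits all 78 slopes had the same sign, at a median of 0.991 and 0.995 of their size, with SEs at a median of 1.04 and 1.14 of theirs. Leaving out 1 library at a time gave between 23 genes (without pregnant replicate 7) and 488 (without pregnant replicate 13). The calls of the 4 identifiers above held without any 1 library (highest edgeR adjusted p = 0.0431), but none of the 4 passed in limma voom (adjusted p from 0.0909 to 0.189) or within a block or an outcome alone. The slope of ENSBTAG00000016819 was 0.87 in limma voom, 1.16 in block 1, 1.13 in block 2, 1.01 in nonpregnant and 1.37 in pregnant cows, and that of ENSBTAG00000004256 lay between 0.43 and 0.52 in the same fits. The slope of ENSBTAG00000049346 lay between -1.35 and -0.99 in them, and that of ENSBTAG00000014555 between -1.84 and -0.94. ENSBTAG00000004256 also missed the threshold with P4 on the linear scale (edgeR adjusted p = 0.0510) and without those 7 libraries (slope 0.52, edgeR adjusted p = 0.0813).

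**Figure D3:**
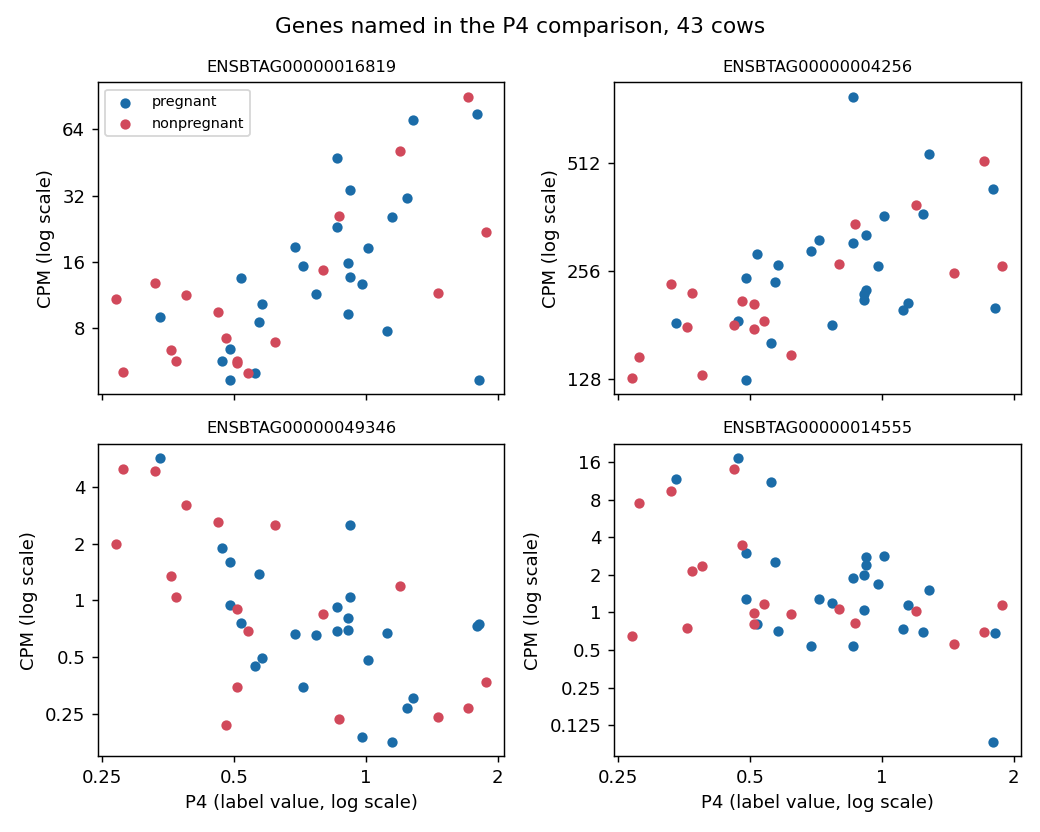
Expression of the 4 genes named in the P4 comparison (CPM, log axes) against P4 (label value, log axis) in the 43 cows, coloured by outcome. ENSBTAG00000016819 and ENSBTAG00000004256 rise and ENSBTAG00000049346 and ENSBTAG00000014555 fall with P4, in cows of either outcome.

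P4 also followed a smaller axis of variation between cows, the fourth principal component. The first 5 principal components held 21.7%, 11.5%, 9.08%, 5.86% and 4.40% of the variance of log2 CPM. Scores on the fourth correlated with log2 P4 (Pearson r = 0.52, permutation p = 0.00041, adjusted p = 0.00615 over 15 tests of components; Spearman rho = 0.53, permutation p = 0.00035, adjusted p = 0.00175 over the rank correlations). Without the 2 cows farthest from the median P4, r was 0.53. It was 0.57 in block 1 and 0.45 in block 2. No component differed between outcomes or between blocks past the threshold, and the lowest adjusted p among those tests was 0.609. No gene of the 15206 differed between outcomes in its P4 slope (0 called by edgeR's interaction test and by DESeq2 and limma voom, with 872, 1036 and 1724 at an unadjusted p under 0.05). With no low-count filter that edgeR test called 7 genes, 4 with a higher and 3 with a lower slope in pregnant cows.

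**Figure D4:**
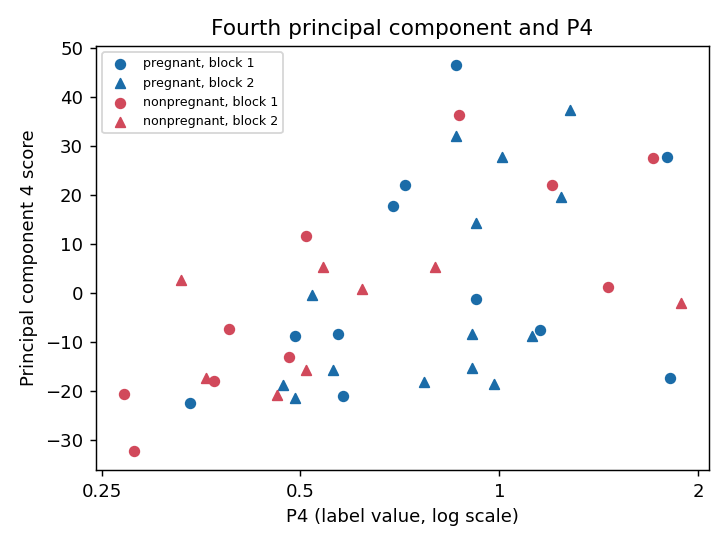
Score on the fourth principal component of log2 CPM (5.86% of the variance) against P4 (label value, log axis), with colour for outcome and marker shape for block. Scores rise with P4 in both blocks (r = 0.57 and 0.45), and the outcomes overlap.

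Between the rounds of synchronization, 63 genes differed, 53 higher and 10 lower in block 2 (edgeR quasi-likelihood with outcome in the model, 22 against 21 cows; median absolute log2 fold change 0.62). ENSBTAG00000022185 averaged 41.0 ± 8.79 CPM in block 1 and 64.8 ± 18.999 CPM in block 2 (SD), a 1.62-fold rise (log2 0.69 ± 0.11 SE; edgeR adjusted p = 0.000454). ENSBTAG00000043250 averaged 61.3 ± 37.3 CPM in block 1 and 27.1 ± 18.3 CPM in block 2 (SD), a log2 change of -1.21 ± 0.25 (SE; edgeR adjusted p = 0.0205). ENSBTAG00000008182 rose by 3.82 ± 0.58 on the log2 scale (SE; edgeR adjusted p = 0.000454). Its medians were 2.13 and 8.26 CPM, and 9 of 22 cows of block 2 but 0 of 21 of block 1 exceeded 10 CPM, and limma voom gave 2.14 (adjusted p = 0.0123). ENSBTAG00000037644 fell by 7.93 ± 1.22 on the log2 scale (SE; edgeR adjusted p = 0.000454). That fold rested on 6 of 21 cows of block 1 above 10 CPM, with medians of 0.838 and 0.194 CPM, and limma voom gave -3.18 (adjusted p = 0.312). It was -5.92 in DESeq2 and -6.02 without pregnant replicate 5 (edgeR adjusted p = 0.00416). Cows of block 2 had on average 264 more detected genes (permutation p = 0.0557). With that number in the model 6 genes passed, while all 63 fold changes kept their sign at a median of 0.921 of their size. The 63 genes were chosen on these same cows, which favours kept signs. DESeq2 called 229 genes and limma voom 834. The count was 12 without the 7 libraries richest in their 10 most abundant genes, where all 63 fold changes kept their sign at a median of 1.01 of their size, with SEs at a median of 1.11 of theirs. It was between 11 (without nonpregnant replicate 5) and 354 (without nonpregnant replicate 7) when 1 library was left out. None of the 63 genes was among the 78 associated with P4 (0.323 would be shared by independent lists).

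Finally, the libraries were used to predict the outcome of cows left out of the training. The area under the ROC curve, where 0.5 is no better than chance, was 0.342. Of 100 assignments of the outcome within blocks, the real one included, 88 gave an area as large, and the drawn ones had a median of 0.483 and ranged from 0.314 to 0.639 between their 5th and 95th percentiles. P4 alone, ranked without any fit or cross-validation, gave 0.682, and 5 of the 100 assignments gave as large a value, counted in 1 direction. That area restates the comparison of P4 ranks between outcomes and is not separate evidence.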

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

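Tests within a block or outcome, with total counts, detected genes or the share of the 10 most abundant genes as a covariate, without libraries over 8% in that share, or without 1 library were chosen after the data were seen. The outcome comparison called 0 genes under each setting and without each library, except with no low-count filter (5, all lower in pregnant cows). P4 by outcome kept its direction and passed the threshold only on ranks, 7.84 ranks higher in pregnant cows (permutation p = 0.0449). The outcome-by-block interaction called 0 genes under each alternative, and the P4-by-outcome interaction called 7 with no low-count filter and 0 under the others. The area under the ROC curve ranged from 0.311 to 0.348.

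The 78 genes associated with P4 became 276 with DESeq2, 0 with limma voom, 181 with no low-count filter, 14 with outcome as a covariate, 26 with P4 on the linear scale, 124 with its rank, 264 without the 2 cows of highest P4, 194 with the share of the 10 most abundant genes as a covariate and 7 without the 7 libraries over 8%. Block 1, block 2 and pregnant cows alone called 0 and nonpregnant cows alone called 1. The other settings stayed within 1.5 times. In limma voom all 78 slopes kept their sign at a median 0.878 of their size, and their median adjusted p was 0.145; the cause was not tested. Without 1 library the count ran from 23 to 488. It was 23, 51, 44, 37 and 30 without pregnant replicates 7, 10, 11, 14 and 23, and 235 and 488 without pregnant replicates 12 and 13. It was 49, 47, 47, 30, 45, 25, 51 and 39 without nonpregnant replicates 1, 3, 6, 7, 10, 13, 14 and 15, and 164, 122 and 129 without nonpregnant replicates 5, 8 and 16.

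The 63 genes that differed between blocks became 229 with DESeq2, 834 with limma voom, 30 without the pregnancy term, 179 with log2 total counts, 6 with the number of detected genes and 12 without the 7 libraries over 8%; the cause was not tested. In the fits calling 30, 6 and 12, all 63 kept their sign at a median 0.956, 0.921 and 1.01 of their size, but they were chosen on these same cows. Without 1 library the count ran from 11 to 354. It was 34, 38, 41, 38, 35, 31, 28, 34 and 41 without pregnant replicates 5, 9, 10, 12, 14, 15, 18, 20 and 21, and 110 without pregnant replicate 8. It was 38, 40, 11 and 22 without nonpregnant replicates 1, 2, 5 and 10, and 354, 203, 120, 249 and 170 without nonpregnant replicates 7, 8, 11, 12 and 18.

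RLE factors moved the median log2 fold change of all genes by less than 0.01. No paired analysis was possible because each cow was sampled once and replicate numbers only name the cows. Gene list tests and list covariates were not run, for want of symbols, nor was leaving out libraries under 50% of the median total, as there were 0.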

Other observations

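An exploratory look at the counts came before the tests below were written down. Chosen only after the result was seen were the reassignments for the counts of 0 genes, the correlation between blocks, the covariate of detected genes, the spread of P4, the grouping of cows by P4, the modules with their tests against detected genes and the genes with a gap. The readings of a missed threshold as open were also set after the values were seen, for the share of signs between blocks, an outcome difference beyond P4 and the spread of expression.

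Among the 3000 most variable genes, 9 groups of co-expressed genes (modules) held 1532 genes. The module of 45 genes was higher in block 2 by 0.777 in the mean z-score of its genes (permutation p = 0.00066, adjusted p = 0.0178 over 27 tests). That module also rose with the number of detected genes per library (Pearson r = 0.53, permutation p = 0.00029, adjusted p = 0.00129 over 9 modules; Spearman rho = 0.48, permutation p = 0.00112, adjusted p = 0.0101), which averaged 264 higher in block 2. Its r was 0.48 without the 2 libraries farthest from the median, 0.53 in block 1 and 0.35 in block 2. At equal numbers of detected genes its block difference was 0.588 (permutation p = 0.00327, adjusted p = 0.0294 over 9 modules). The modules of 70 and 599 genes also rose with detected genes (Pearson r = 0.61 and 0.52, permutation adjusted p = 9.0e-05 and 0.00129). Their Spearman rho was 0.46 and 0.38 (permutation adjusted p = 0.0107 and 0.0367). For the 70 genes r was 0.44 without the 2 libraries farthest from the median, 0.71 in block 1 and 0.34 in block 2. For the 599 genes it was 0.38, 0.78 and 0.05 in that order, so their link was not seen in block 2. Neither of these modules differed between blocks past the threshold. The module of 86 genes followed log2 P4 by rank (Spearman rho = 0.47, permutation p = 0.00166, adjusted p = 0.0149 over the rank correlations of 9 modules). It missed the threshold by Pearson's r (0.43, permutation p = 0.00376, adjusted p = 0.0508 over 27 tests). The 2 adjusted values come from families of unlike size, so their contrast does not separate the 2 measures. The r of the 86 genes was 0.41 without the 2 cows farthest from the median P4, 0.51 in block 1 and 0.39 in block 2. No module differed between outcomes past the threshold.

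Of the 14 cows of lowest P4, 4 became pregnant, against 11 of 15 in the middle and 10 of 14 of the highest (two-sided Fisher's exact p = 0.0570, lowest against highest). Log2 P4 had an SD of 0.60 in pregnant and 0.88 in nonpregnant cows (permutation p of the ratio of SDs = 0.0319). In the same order the SDs were 0.75 and 0.99 in block 1 and 0.49 and 0.79 in block 2. The permutation did not remove the difference in mean log2 P4 between outcomes. It therefore cannot tell a difference in spread from one in level, and a tie of outcome to the spread of P4 stays open. Libraries lay on average 78.9 from their centroid in pregnant and 84.4 in nonpregnant cows, in log2 CPM over all tested genes. Of 100 splits of the outcome, 34 gave as large a difference, which leaves a difference in spread open.

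Expression of 2 genes fell into separate levels with a gap of at least 4 on the log2 scale and at least 5 cows on each side. ENSBTAG00000009656 was at or under 0.183 CPM in 11 cows and at or over 13.5 CPM in 32, and 7 of the 11 became pregnant. ENSBTAG00000040367 was at or under 1.88 CPM in 28 cows and at or over 70.1 CPM in 15, and 16 of the 28 became pregnant. Neither gene's levels differed by outcome or block past the threshold (Fisher's exact p = 1 in each case), and the gap rule replaced a looser one after its genes were seen.

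No gene passed between the outcomes, a count that 100 of 100 splits must reach (highest other 17), and 63 of 100 splits within blocks gave as many genes at an unadjusted p under 0.05 as the real 455. A candidate explanation is that the difference runs in opposite directions in the blocks, and the correlation of the blocks' fold changes was -0.14, as low in 20 of 100 splits, which leaves that open. The 78 genes associated with P4 had a mean outcome fold change, signed by their slope, of 0.18 (10 of 100 splits as large). These genes and signs were chosen by P4 on the same cows, and P4 averaged higher in pregnant cows. That value is therefore not separate evidence from the comparison of P4 between outcomes. With P4 in the model the mean signed fold change was -0.0089 (57 of 100). By the rule written before this test, a value under the top 0.05 of splits counts against a difference beyond that of P4. That top began at 0.118, so by the rule the value counted against such a difference. The value lay near the median of the drawn splits (0.0131). The top is a threshold for a call and not an upper bound, and no interval was computed. A mean difference in these 78 genes was therefore not seen, and its possible size was not bounded. A missed threshold does not show that there is none. For the interactions with block and with P4, whose 0 is likewise reached by 100 of 100 splits (highest others 9 and 1782), 47 and 44 of 100 gave as many genes at an unadjusted p under 0.05.

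P4 reassigned among the cows within blocks called at least 78 genes in 3 of 100 assignments, the real one included, but 5 of 100 gave as many genes at an unadjusted p under 0.05, so chance is argued against by the first count and not by the second. The others that reached 78 called 2872 and 1485, many times the real count, which may reflect structure shared by groups of libraries and was not tested. Library depth or the share of the most abundant genes could be a source, but the slopes kept a median of 0.998 of their size with those covariates. Slopes in 1 block only stay open. Genes were picked within 1 block by unadjusted p, as no gene passed there after adjustment, and P4 was reassigned in the other block only. Of the 244 genes picked in block 1, 77.0% had the same sign in block 2, as large a share in 7 of 100 assignments. Of the 1306 genes picked in block 2, 75.6% had the same sign in block 1, as large a share in 17 of 100. Across all 15206 genes the P4 slopes of the blocks had a correlation of 0.12, as large in 30 of 100. An effect of P4 itself, or of cell types that change with it in the brush sample, was not separated from other differences between the cows.

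Block labels reassigned within outcomes called at least 63 genes in 2 of 100 splits, the real one included, with a highest other of 268, but 6 of 100 gave as many genes at an unadjusted p under 0.05, so chance is argued against by the first count and not by the second. Depth or the most abundant genes could contribute, but the fold changes kept a median of 0.996 of their size with those covariates. With the number of detected genes they kept 0.921, with SEs at a median of 1.05 of theirs. Then 6 genes passed while all 63 kept their sign, but the 63 were chosen on these same cows. Season, handling and library preparation may each differ between the rounds and were not tested.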
